A study of Homo sapiens with 15 samples.

How the data were processed

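HA-tagged GLIS3 was measured by ChIP-seq, which sequences DNA bound by a protein after pull-down with an antibody, in doxycycline-treated G3-hESCs 12 h after neural progenitor induction. Sheared chromatin was pulled down with an HA antibody on magnetic beads and sequenced from TruSeq ChIP libraries, per the labels' protocols. The file analysed is the authors' list of binding sites. Each sample was assigned to a group from its title. The site list was assigned to the HA ChIP with doxycycline because its name gives that treatment and tag. The values analysed here come from 1 ChIP library, and the RNA-seq libraries were not analysed here, so no test between groups was run.

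Reads were aligned with Bowtie to hg19, per the submitters' processing notes, and the version of Bowtie is not given in the sources used here. Sites were called with SISSRs 1.4 at a p threshold of 0.001 against a control library, per the file headers. The header names that control by an internal code, and which of the study's libraries it was is not given in the sources used here. SISSRs finds points where tags on the sense strand give way to tags on the antisense strand. The caller used a scanning window of 20 bp, a fragment length of 150 bp and a mappable share of the genome of 0.80, and needed at least 2 directional tags on each side of a site, per the file headers. It kept 1 tag per genomic position, which left 49105565 of 52866042 ChIP tags (92.89%), per the file headers. The control library had 78999629 tags, and the header does not say whether repeated positions were removed from it. A site needed at least 22 tags and a fold of at least 18, per the file headers.

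Tag counts in the deposited list are whole numbers of ChIP tags per site, not normalized. The fold is the authors' ratio of ChIP tags to control tags. Its values at sites of 40 and 60 bp equal the ChIP tag number over a whole control tag number times 0.6216, the ratio of selected ChIP tags to control tags in the header. At the 3933 wider sites only 63.8% gave a whole number within 0.02, so control tags were used only for sites of 40 or 60 bp. The p-value in the deposited list is the caller's own, with no adjustment for multiple tests stated in the header. It never rose with increasing fold, so a stricter p acts as a higher fold threshold. Because 1 tag was kept per position, tags that fall on a used position are not counted, and how far this lowers the tag numbers of strong sites was not measured. Site starts and ends are given as the list has them. Positions lie on a grid of 20 bp.

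The genome length in the header equals the sum of hg19 chromosomes 1 to 22, X and Y exactly. Chromosome lengths came from the hg19 table of GenomeInfoDb 1.38.1 and bands from the band table of circlize 0.4.16, whose chromosome ends match hg19 for 24 of 24 chromosomes. The 7 sites outside chromosomes 1 to 22 and X entered no test. Sites were counted in the band that holds their midpoint. Analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

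Densities carry exact 95% Poisson intervals, shares carry exact binomial (Clopper-Pearson) intervals, and ratios of counts carry intervals from the exact binomial share of the first count. PCR reads without molecular identifiers are not independent molecules, so all intervals cover counting error only. Places of sites were compared with 1000 random placements on the same chromosome outside centromeric, heterochromatic and stalk bands, and with 1000 rotations of each chromosome, which move all its sites by 1 random distance. Spacing was compared with 1000 placements within the whole chromosome and within each band. Monte Carlo p-values are two-sided, except that of the chi-square, and count the observed value. In 20 simulated lists of 18720 sites with equal density, 1 gave a p of at most 0.05 for light bands. In 20 lists with light bands 3 times as dense, all 20 did, and the recovered ratio averaged 2.99. The simulated sites were drawn independently and tested with fewer placements, so these lists do not show how the test behaves with clustered sites.

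The site summary, chromosome densities, spacing against placement within chromosomes, and clusters were fixed before the data were examined. The placement of sites within bands for the spacing, the tests on bands and chromosome ends, the strength of sites by place, and the comparison of chromosome 1 were added after. The rule for naming sites, fixed before the data were examined for the case without gene annotation, takes the 10 sites with the most tags and the 10 with the highest fold, with ties broken by the other measure. Alternatives were stricter p, joining of neighbours, other distances, other random placements and leaving out chromosomes. Tests that need an hg19 sequence or gene annotation were not run. These were the distance to transcription starts, fixed gene lists and binding motifs, including motifs by site strength. GRCh38 gene positions were not used, since the sites are on hg19.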

Results

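GLIS3, a Krüppel-like zinc finger transcription factor, was mapped with an antibody against its HA tag in G3-hESCs, a line made from the human embryonic stem cell line H9 in which doxycycline switches on GLIS3. Cells were taken 12 h after neural progenitor induction, in a medium with inhibitors of the activin, TGF-beta and BMP pathways. The series held 15 samples, each the only member of its group. These were 4 chromatin libraries at 12 h (HA ChIP and input DNA, each with and without doxycycline) and 11 RNA-seq libraries, 6 without doxycycline from 0 h to 7 days and 5 with it from 12 h to 7 days. The data analysed here were the authors' list of HA-GLIS3 sites in doxycycline-treated cells. The RNA-seq libraries and the HA ChIP without doxycycline were not analysed here, so neither the effect of doxycycline nor a change of expression was measured. The ChIP library behind the list had 52866042 tags, of which the caller used 49105565, and the control library had 78999629 tags. With 1 library there was no replicate error, and every interval given covers counting error only.

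HA-GLIS3 sites were called at many places spread over the genome. The list held 18727 sites, and 18720 of them lay on chromosomes 1 to 22 and X. The median site had 79 ChIP tags, with quartiles of 48 and 126 and a range from 22 to 301. The median fold over the control library was 31.8, with quartiles of 23.2 and 47.2 and a range from 18.02 to 460.1. Site width was 40 bp at 11866 sites and 60 bp at 2928 sites, and reached 800 bp. These widths are the caller's, on its grid of 20 bp, and do not measure the length of DNA bound. Fold and p are the authors' values from the caller. Every site passed a p of 0.001, 3871 sites (20.7%) had a p of at most 1e-04, which needed a fold of 51.7, and 505 sites (2.70%) had a p of at most 1e-05, which needed a fold of 116.4. Tags summed over sites came to 3.59% of the tags used, an upper limit because neighbouring sites can count the same tag.

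The fold rested on few control tags. At the 14794 sites of 40 or 60 bp, dividing the ChIP tags by the fold and scaling by library size returned a whole number of control tags at 100% of sites, to within 0.02 tags. The median was 4 control tags, and the range was 1 to 19. At 1274 of these sites (8.61%) the control tag number was 1. A value of 0 did not occur, so a 1 may stand for no tag.

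The 10 sites with the most tags had 298 to 301 tags, and 7 of them lay in light Giemsa bands. These tag numbers differ by less than their counting error, and they may also be capped by the rule of 1 tag per position. The order of these sites was thus not resolved. None of them was among the 10 sites with the highest fold. A site with 301 tags was at chromosome 20, 62035631 to 62035671 (band 20q13.33), with a fold of 121.06 (95% interval 46.8 to 447.2, from 4 control tags). Sites with 301 tags were also at chromosome 19, 501771 to 501811 (19p13.3), with a fold of 53.80, at chromosome 17, 46072791 to 46072831 (17q21.32), with a fold of 40.35, and at chromosome 1, 16442331 to 16442551 (1p36.13), with a fold of 34.13. Sites with 300 tags were at chromosome 1, 228252111 to 228252171 (1q42.13), and chromosome 4, 919851 to 919891 (4p16.3). Sites with 299 tags were at chromosome 7, 30910611 to 30910651 (7p14.3), chromosome 12, 132973971 to 132974091 (12q24.33), and chromosome 1, 2466291 to 2466351 (1p36.32). A neighbour at chromosome 12, 132974231 to 132974271, had 298 tags and a fold of 119.85. As neighbouring sites can count the same tag, these sites on chromosome 12 may be 1 region counted again.

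The 10 sites with the highest fold had folds from 337.8 to 460.1 on 210 to 286 tags, and 7 of them lay in light bands. The first was at chromosome 18, 12285151 to 12285191 (18p11.21), with 286 tags and a fold of 460.11 (95% interval 81.9 to 18236). It was followed by chromosome 2, 28762891 to 28762951 (2p23.2), with a fold of 416.67, and chromosome 10, 120739851 to 120739891 (10q26.11), with a fold of 381.28. Next came chromosome 13, 114765491 to 114765611 (13q34), with a fold of 378.06. Both chromosome 11, 1145851 to 1145891 (11p15.5), and chromosome 11, 2953151 to 2953191 (11p15.4), had a fold of 368.41. The others were at chromosome 14, 103621791 to 103622011 (14q32.32), chromosome 20, 34693911 to 34693951 (20q11.23), chromosome 3, 149216671 to 149216711 (3q25.1), and chromosome 9, 139230871 to 139230911 (9q34.3). All 8 of these sites whose control tags could be recovered had 1 control tag, so their order was not resolved at this depth. Whether a site lay in a gene, exon, intron or UTR, or near a WNT gene as the series title asks, was not determined, because no hg19 gene annotation was used here.

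HA-GLIS3 sites were unevenly shared among chromosomes. Chromosome 19, known as gene-dense, had 21.4 sites per Mb (95% Poisson interval 20.3 to 22.6), and chromosome 13, known as gene-poor, had 2.23 (1.97 to 2.52), a ratio of 9.60 (8.39 to 11.02). They were picked as the highest and lowest autosomes, and neighbouring sites are not independent, which the interval leaves out. With 1 site kept per cluster of sites within 2 kb, the ratio was 7.95 (6.82 to 9.30). Chromosomes 22, 17, 20 and 16 followed chromosome 19 with 16.4, 16.3, 12.5 and 11.5 sites per Mb. Together these 5 chromosomes held 28.1% of the sites on 11.4% of the length. Chromosomes 4, 18 and X had 2.94, 3.88 and 2.14 sites per Mb, against 6.38 for the 22 autosomes pooled. Chromosomes 3, 5 and 6 were about as low as chromosome 18, with 3.88, 3.94 and 3.91. The chi-square against equal density over the autosomes was 6394 with 21 degrees of freedom, and the highest of 1000 random allocations was 44.3 (Monte Carlo p = 0.000999, the smallest they can give).

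**Figure D1:**
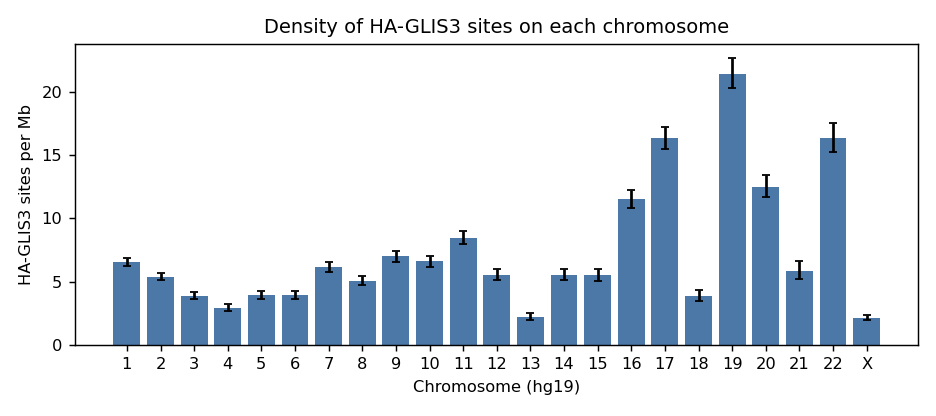
Sites per Mb (vertical axis) on chromosomes 1 to 22 and X of hg19 (horizontal axis), with 95% Poisson intervals as error bars. Chromosome 19 is the highest at 21.4 sites per Mb, and chromosomes X and 13 are the lowest at 2.14 and 2.23.

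Chromosome 1 differed from the rest in tags per site. Its 1626 sites had a median of 115 tags, while the medians of the other 21 autosomes ran from 68 to 80. Control tags at its sites of 40 or 60 bp averaged 6.79 (95% Poisson interval 6.65 to 6.93), against 4.01 to 4.57 on the other autosomes. The median fold on chromosome 1 was 28.7, within the range of 28.2 to 34.4 of the other autosomes. Only sites with a fold of at least 18 were called, so a site with more ChIP tags could hold more control tags. Control tags and fold at called sites are thus not independent of the ChIP tags. Chromosome X had a median of 59 tags, and its control tags averaged 3.25 (3.03 to 3.47), both below the ranges of these autosomes. Rankings by tags favoured chromosome 1, which held 30 of the 100 sites with the most tags and 3 of the 100 with the highest fold, from 8.69% of all sites.

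**Figure D2:**
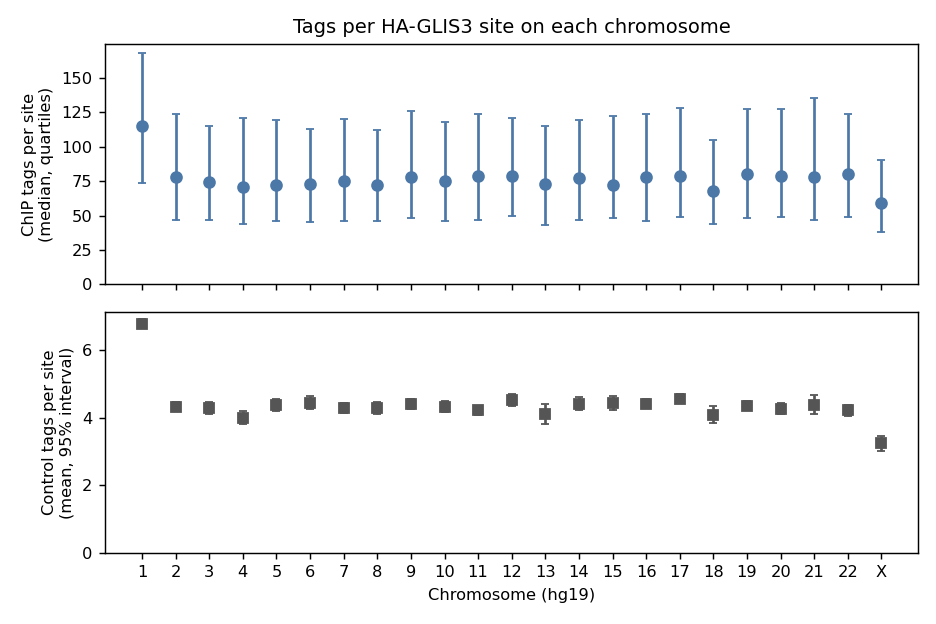
ChIP tags per site (upper panel: points are medians, bars reach the quartiles) and control tags per site of 40 or 60 bp (lower panel: points are means, bars are 95% Poisson intervals) by chromosome of hg19. Chromosome 1 lies above all others in both panels, at 115 ChIP tags and 6.79 control tags.

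HA-GLIS3 sites favoured light bands, the chromosome segments that stay pale after Giemsa staining and are known to be GC-rich and gene-rich. Light (gneg) bands had 10.6 sites per Mb (95% Poisson interval 10.4 to 10.8, 13633 sites) and palest grey (gpos25) bands 10.1 (9.72 to 10.6, 2200 sites). Density then fell with darker staining, to 4.07 in gpos50 bands, 1.79 in gpos75 bands and 0.841 in the darkest (gpos100) bands (0.762 to 0.925, 419 sites). Light bands were thus 12.6 times as dense as the darkest (11.4 to 13.9), an interval that leaves out that neighbouring sites are not independent. Centromeric, heterochromatic and stalk bands had 104 sites, or 0.464 per Mb. Of the 18616 sites in the other bands, 73.2% were in light bands, against 47.1% on average when sites were placed at random on the same chromosome. The highest of 1000 such placements was 48.1%, and the highest of 1000 rotations of whole chromosomes, which keep the spacing of sites, was 54.0% (n = 18616 sites, Monte Carlo p = 0.000999 for both, the smallest they can give). Light bands were denser than the stained (gpos) bands on 23 of 23 chromosomes, by 1.84 times on chromosome 1 up to 8.69 times on chromosome 21.

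**Figure D3:**
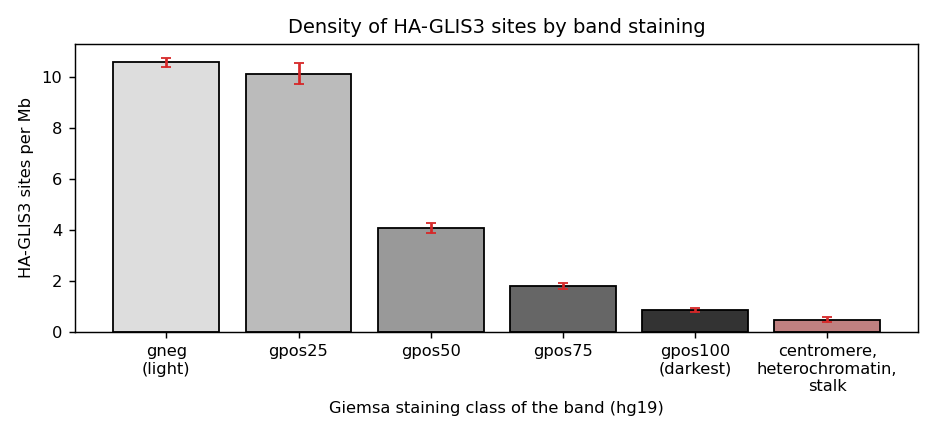
Sites per Mb (vertical axis) in bands of each Giemsa class of hg19 (horizontal axis), with 95% Poisson intervals as error bars. Density is 10.6 in light bands and 0.841 in the darkest bands.

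Sites were also concentrated towards chromosome ends. Within 5 Mb of an end lay 31.6% of sites, against 9.10% on average over random placements, of which the highest was 9.64% (n = 18616 sites, Monte Carlo p = 0.000999, two-sided, the smallest 1000 placements can give). The highest of 1000 rotations was 16.5%. With 1 site kept per cluster of sites within 10 kb, the share was lower, at 22.9%, against 8.705% on average over 200 random placements. In light bands the density was 32.3 sites per Mb within 5 Mb of an end and 7.44 farther away, a ratio of 4.34 (95% interval 4.20 to 4.50). In gpos bands it was 14.8 and 2.94, a ratio of 5.04 (4.63 to 5.48). Neighbouring sites are not independent, which the intervals of both ratios leave out. The excess in gpos bands lay mostly between 2 and 5 Mb from an end, at 16.5 sites per Mb, and within 1 Mb of an end they had 3 sites per Mb (95% Poisson interval 1.37 to 5.70). The density over all these bands was highest between 1 and 2 Mb from an end, at 44.9 sites per Mb, and fell to 3.44 beyond 40 Mb. Among bands of at least 1 Mb, the 10 densest held 12.2% of sites on 1.13% of the length, and 9 of the 10 were the last band of their chromosome arm. These bands were singled out after their values were seen. The densest were 11p15.5 (chromosome 11, 1 to 2800000) with 87.1 sites per Mb (76.6 to 98.8), 7p22.3 (chromosome 7, 1 to 2800000) with 78.6, 16q24.3 (chromosome 16, 88700001 to 90354753) with 77.4, 9q34.3 (chromosome 9, 137400001 to 141213431) with 73.2, and 19p13.3 (chromosome 19, 1 to 6900000) with 63.6.

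**Figure D4:**
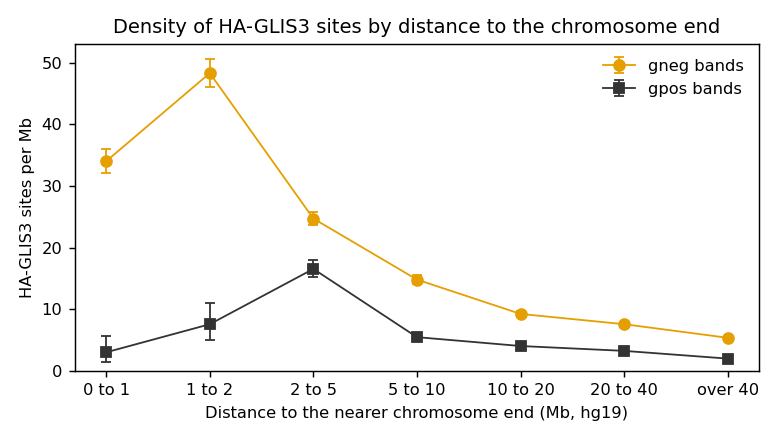
Sites per Mb (vertical axis) by distance to the nearer chromosome end in Mb (horizontal axis), for light (gneg) and stained (gpos) bands of hg19, with 95% Poisson intervals as error bars. Light bands lie above stained bands in each distance class and reach 48.3 sites per Mb between 1 and 2 Mb from an end.

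Sites with a higher fold lay slightly more often in light bands and near chromosome ends. From the bottom to the top quartile of fold, the share in light bands rose from 70.0% (95% exact interval 68.7 to 71.3) to 75.5% (74.3 to 76.8), and the share within 5 Mb of an end rose from 26.4% to 37.6%. The share in gpos100 bands fell from 2.70% to 1.82%. Odds ratios of the top against the bottom quartile were 1.32, 1.68 and 0.667, with adjusted p of 4.26e-09, 1.81e-30 and 0.00433 (Fisher's exact test, two-sided, Benjamini-Hochberg over 6 tests). By tag number, top against bottom quartile, the 3 shares differed in the same directions, with odds ratios of 1.199, 1.17 and 0.369 and adjusted p of 0.000156, 0.000452 and 3.5e-11. The share near ends did not rise steadily with tag number: it was 31.04%, 29.5%, 30.8% and 34.49% from the bottom to the top quartile. Sites are not replicate cultures and neighbours are not independent, so these p-values describe this list.

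Neighbouring sites lay close together. Of the 18697 gaps between neighbours, 24.9% were at most 2 kb, against 1.73% for random placement on the same chromosome and 4.72% for random placement within the same band, a comparison added after the data were seen. The highest of 1000 placements was 2.10% and 5.23%, respectively (n = 18697 gaps, Monte Carlo p = 0.000999 for both, two-sided, the smallest they can give). Neighbouring calls can be 1 region split by the caller, which random placement does not reproduce. Joining calls within 500 bp left 16781 of the 18727 sites, and separate sites were not told apart from split calls. Joining sites within 2 kb gave 3059 clusters with 7711 sites (41.2%), beside 11009 single sites. There were 2098 clusters of 2 sites, 814 of 3 or 4 sites and 147 of 5 or more, and 130 of those 147 were in light bands. The number of clusters was 1566 with joining at 500 bp and 334 among sites with a p of at most 1e-04. The median site in a cluster had 90 tags and a fold of 33.8, against 72 tags and a fold of 30.3 for single sites. The largest clusters, singled out after their values were seen, had 12 sites each, at chromosome 20, 60937011 to 60947771 (20q13.33), and chromosome 1, 868891 to 879831 (1p36.33). The cluster at chromosome 10, 134950111 to 134953091 (10q26.3), had 11 sites.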

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

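Outside the assembled chromosomes, the list had 6 sites on 3 contigs that are not placed within a chromosome sequence, above the caller's control with folds from 19.3 to 51.5 on 24 to 79 tags. They were noticed because no comparison used them. Of these, 4 were on the contig 17_gl000204_random.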

How the results depend on the processing

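No paired analysis was possible because the values analysed here come from 1 ChIP library, which also leaves no replicate to leave out. The list shrank to 3871 sites at a p of at most 1e-04 and to 505 at 1e-05. Minimums of 20 tags or 10-fold removed no site, so they test nothing, and joining within 500 bp left 16781. The number of clusters was 1566 with joining at 500 bp and 334 at the stricter p of 1e-04, against 3059, and 3615 with joining at 10 kb. The ratio of density between chromosomes 19 and 13 was 7.95 with 1 site per 2 kb cluster and 7.76 at a p of at most 1e-04, against 9.60, and between 8.44 and 10.1 under the other 3 alternatives, and the cause was not tested. The 4 alternatives for close spacing joined no neighbouring calls, so they cannot tell separate sites from 1 region split by the caller. Close spacing stayed past the threshold under all 4 alternatives, with 10.6% to 25.1% of gaps at most 2 kb. The preference for light bands did so under all 9 alternatives (68.1% to 78.8%). The preference for chromosome ends did so under all 7 (22.9% to 38.8% within 5 Mb, 16.9% within 2 Mb and 42.5% within 10 Mb). The lowest share within 5 Mb, 22.9%, came with 1 site per 10 kb cluster. Each alternative for spacing, bands and ends used 200 placements, whose smallest p is 0.00498. For spacing and light bands, leaving out the 1% of sites with the most tags removed too few sites to change the outcome. The rotations, used for light bands and ends, repeat a comparison given above. Adding 1 control tag to every site left 11576 of the 14794 sites of 40 or 60 bp at the caller's fold, and scaling by all ChIP tags left 13537. Chosen after seeing the data were the alternatives for bands and ends, those without chromosome 1, those on control tags, placement within bands for the spacing, and, for the density ratio, a p of at most 1e-05 (8.44) and lengths without centromeric, heterochromatic and stalk bands (10.1). Of 30 alternatives chosen before the data were examined, 17 belong to the 4 tests that need an hg19 sequence or annotation and 1 needed assembly gaps, and these were not run.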

Other observations

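In the tests of this part, the joining of sites into 10 kb clusters and the random removal of tags on chromosome 1 were set before their results were seen, and the others after. Sites were concentrated in light bands, and 3 technical explanations were weighed. Split calls of the same region do not account for it, since with 1 site per 10 kb cluster 68.1% of sites were still in light bands, above the highest of 1000 rotations (52.5%). Extra copies of whole chromosomes do not either, because light bands were denser on 23 of 23 chromosomes. Nor do weak calls near the threshold, as the share in light bands was 75.5% in the top quartile of fold and 70.0% in the bottom quartile. A bias of the ChIP library towards GC-rich DNA relative to its control, and open chromatin or a G-rich binding motif as biology, remain open and untested, because neither the sequence nor the HA ChIP without doxycycline was analysed here.

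Chromosome 1 had a median of 115 tags per site, 1.51 times the median of the other autosomes, and 1.56 times their mean control tags. A longer counting window, or repeated tags kept on this chromosome alone, is argued against by the highest tag number, which was 301 both there and elsewhere (a ratio of 1). A gain of 1 arm or part is argued against too, since medians were 117 on the short arm and 105 on the long arm, and 18 of 20 bins of 10 Mb with at least 10 sites lay above the highest median of the other autosomes. A candidate explanation is an extra copy of the whole chromosome in these cells, which would raise ChIP and control tags alike. Control tags were known only at called sites, where the fold limit lets sites with more ChIP tags hold more control tags. This limit can add to the rise in control tags, and by how much was not tested, so that rise is not separate evidence. An extra copy would also raise the highest tag number, unless the rule of 1 tag per position caps that number, which was not tested. The tags at its sites of 40 or 60 bp (median 122) were thinned at random to 66.7% and the caller's limits applied again. Then 86.3% of sites stayed, with a median of 89 tags and a median fold of 32.6. Of 100 draws, 83 fell inside the range of the other autosomes (70 to 89 tags, 27.9 to 35.4 fold). The thinning took tag numbers as proportional to copies, which the rule of 1 tag per position may break at strong sites. It neither excludes an extra copy nor tells it from a difference in mapping.

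Tag numbers reached 301 at most, on chromosome 1 and elsewhere (a ratio of 1). The caller kept 1 tag per position and used a fragment length of 150 bp. Whether this rule caps the tag number of a site was not tested, so 301 is not read as a limit of GLIS3 binding. On chromosomes other than 1, 1631 sites had 150 to 199 tags, 780 had 200 to 249 and 280 had 250 to 299.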
